A study of Homo sapiens with 49 samples.

How the data were processed

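Messenger RNA levels were measured on Affymetrix oligonucleotide arrays with 54675 probe sets in 6 lines derived from diffuse large B-cell lymphomas. Per the labels, the lines were grown in RPMI medium and exposed to doxorubicin at 2.5 or 0.00061 µg/mL or left untreated, total RNA was extracted, and biotin-labelled cRNA was made with a 3' in vitro transcription kit. The deposited values are log2 intensities. The values were made with RMA (background correction, quantile normalization between arrays and summary per probe set) in the affy package under R 3.0.2, per the submitters' processing notes. The log2 scale is arbitrary, so that only differences between arrays were interpreted. All 49 arrays were used, and every deposited column was matched to a sample, with 0 left over. The log2 values ran from 1.71 to 14.8, and the median over probe sets of each array lay between 4.84 and 5.04. An array gives no count, so that the number of arrays limits the precision.

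Probe sets were assigned to genes with the platform annotation. Of the 54675 probe sets, 41097 listed 1 gene, 1801 listed several and 11777 listed none. The array also holds 62 Affymetrix control probe sets, which are part of these counts. Only probe sets with 1 gene were used for the comparisons, which left 19775 genes. Where a gene had more than 1 probe set (10523 genes), the probe set with the highest mean over the 49 arrays stood for it. The gene identifier was found in the RefSeq table of assembly GRCh38.p14 for 41043 of the 41097 probe sets, and this table also gave the span of each gene.

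Samples were grouped by the dose and time in their titles. Each line had 1 array per dose and time, so that the line was the replicate and the untreated array of the same line and time was the control. Only lines with both arrays entered a comparison. Each comparison was fitted with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), with the line as a block and moderated variances that followed the expression level. P-values were adjusted by the Benjamini-Hochberg method over the 19775 genes, and a gene was called at an adjusted p below 0.05. Counts at a log2 difference of at least 1 (2-fold) are given beside the main counts. Changes of the effect with time, and differences between lines sampled at 48 h and the other lines, were tested with limma on each line's own difference. The lines were not said to have been cultured more than once, so that no p measures the spread between repeated cultures. The limma p of a gene rests on the spread between lines and on variance borrowed from all genes. At 2.5 µg/mL and 48 h the fit had 1 residual degree of freedom. With those borrowed the median was 12.7 against untreated cells and 62.5 against the low dose. There neither this p nor the standard error measures the spread between lines alone.

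The size of a line's response was the standard deviation (SD) over genes of its log2 difference from its untreated array, compared between doses and times by an exact two-sided sign-flip permutation test over lines. A total of 21 gene lists were fixed with the comparisons, the alternatives and the rule for named genes before the data were examined: p53 targets, the BCL2 family, immediate early genes, G2 and mitosis, G1/S and replication, DNA damage response and repair, NF-kB targets, type I interferon response, unfolded protein and integrated stress response, heat shock, oxidative and iron response, B-cell identity and B-cell receptor, germinal centre markers, activated B-cell markers, plasma cell genes, ribosome biogenesis, respiratory chain, ribosomal proteins, zinc finger (ZNF) genes, replication-dependent histones, and doxorubicin transport, metabolism and targets. In addition, 5 short sets of markers of other cell types were fixed (T cell, myeloid, erythroid, fibroblast and epithelial). Each list was tested against all other genes with camera from limma. The inter-gene correlation was preset at 0.01 or, as an alternative, estimated. Each p was adjusted over the 21 lists of a comparison. With the preset correlation genes, not lines, are the units, so that this p does not measure the spread between lines. With an estimated one the test has only the residual degrees of freedom of the fit. At 2.5 µg/mL against untreated cells these were 5, 4 and 1 at 2, 12 and 48 h. Hardly any list could pass it at 48 h. Members called with adjustment over the list alone were counted beside those called over all genes.

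The genes named per comparison were the 12 largest rises and the 12 largest falls (8 and 8 at 48 h, for time differences and for the untreated time course). They were taken among called genes that differed the same way in every line and whose mean in the higher group lay above the median gene's mean of 5.83. Up to 4 members of each list with the smallest adjusted p, and a set of single genes of interest whatever their result, were added. The set held 14 genes, of which 12 had a value. Where no gene was called, the 3 smallest p-values are given as values only.

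Alternatives changed a single choice at a time, except that leaving out RIVA or U2932 at 2.5 µg/mL and 48 h left 1 line and so also took the joint fit: the mean of all probe sets of a gene, only genes above the median level, arrays centred on their medians, variances without a trend, a joint fit of all 49 arrays, no block for the line, the untreated array at 0 h as the control, a 2-fold minimum, and each line left out in turn. Scaling each array to its poly-A control transcripts or to its hybridization control transcripts, by the mean of their probe sets, was chosen after seeing the data. The fits and list tests were tested on simulated data in which 200 of 19775 genes had been changed by 0.5 or 1 on the log2 scale. The noise was drawn independently for each gene, so that the list tests were not tried under correlation between genes. Every simulated comparison had the noise of the fit at 0.00061 µg/mL and 12 h. The real median standard error was 0.0791 in that fit. At 2.5 µg/mL it was 0.0858, 0.205 and 0.437 at 2, 12 and 48 h, with 6, 5 and 2 lines. The shares recovered at 2.5 µg/mL therefore hold for less noise than the data had. The pairing of arrays was checked from correlations of each line's profile after subtraction of the mean over lines. Same-line correlations were 0.562 or higher and those between different lines 0.0159 or lower in the comparisons at 2 and 12 h. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Probe sets that list several genes were left out because their signal cannot be assigned.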

Results

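Doxorubicin, an anthracycline that intercalates into DNA and traps topoisomerase II, was tested on 6 lines of diffuse large B-cell lymphoma, an aggressive tumour of mature B cells: FARAGE, NU-DHL-1, OCI-Ly7, RIVA, SU-DHL-5 and U2932. Untreated cells were profiled at 0, 2 and 12 h in all 6 lines and at 48 h in 3 (OCI-Ly7, RIVA and U2932). At 0.00061 µg/mL there were 6 arrays at 2 h, 6 at 12 h and 3 at 48 h. At 2.5 µg/mL there were 6 arrays at 2 h, 5 at 12 h (none of SU-DHL-5) and 2 at 48 h (RIVA and U2932). The title of the series names concentration, exposure time and intrinsic sensitivity as the sources of variation. The labels give no sensitivity class for a line, so that only concentration and time were compared directly. Differences below are means over lines of log2 (treated minus untreated of the same line and time), with the limma standard error after ±.

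All directions are relative to the bulk of the genes on an array, because the deposited values were quantile normalized. By the median over their probe sets in each pair, the poly-A control transcripts were brighter at 2.5 µg/mL than on the untreated arrays. The difference was 0.141 ± 0.131 (SD, n = 6) at 2 h, 1.87 ± 0.562 (SD, n = 5) at 12 h and 3.25 ± 0.366 (SD, n = 2) at 48 h. At 2 h the pairs ran from -0.0620 to 0.302, mostly inside the range of -0.250 to 0.247 at the low dose. Arrays were scaled by the mean over these probe sets, which moved more at 2 h (in OCI-Ly7 from 6.87 to 7.54, where the median difference was -0.0620). With arrays so scaled, the difference of the median gene went from 0.02 to -0.28 at 2 h, from 0.20 to -1.59 at 12 h and from 0.17 to -3.07 at 48 h. Untreated arrays at 2 h against 0 h put it at 0.264 on this scale, a shift of like size without the drug. On that scale 7548 genes at 2 h, 19106 at 12 h and 19237 at 48 h were called lower. The scaling takes 1 value per array from every gene, so that these counts and calls repeat a shift measured once per array. They are not evidence gene by gene. The p-values on that scale became implausibly small, such as an adjusted limma p of 2.34e-42 for IER3 at 2 h from 6 lines. Of the genes called higher as deposited, 299 of 796 at 2 h, 112 of 3591 at 12 h and 112 of 1119 at 48 h stayed above 0. The 24 largest rises and falls named at 2 h, the 24 at 12 h and the 16 at 48 h kept their direction and their call. The scaling lowered every difference alike, so that the falls could not turn, and the rises had been picked as the largest. Scaled to the hybridization controls instead, the median gene moved less, to -0.46 at 12 h and -1.28 at 48 h. Medians of lists and other genes that turn below 0 in what follows do so on the poly-A scale. Their signs on the smaller shift were not examined.

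**Figure D1:**
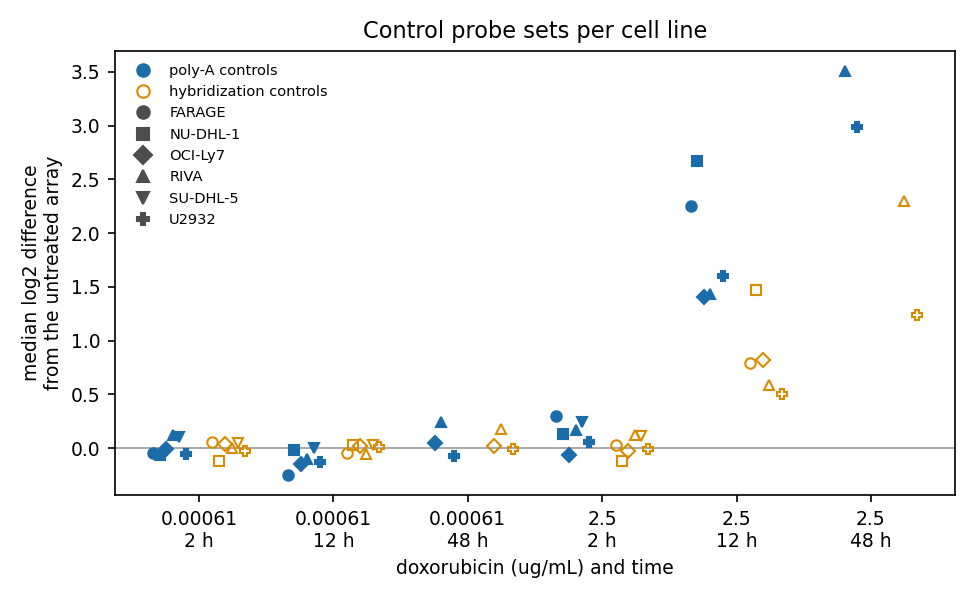
Median log2 difference of the poly-A (filled) and hybridization (open) control transcripts of each line from its untreated array, by dose and time. At 2.5 µg/mL the poly-A controls were 1.41 to 2.67 brighter at 12 h, against -0.250 to 0.247 for all pairs at 0.00061 µg/mL.

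The first question was how far the whole profile moved with dose and time. After 2 h at 2.5 µg/mL the SD over genes of the log2 difference was 0.272 ± 0.0374 (SD, n = 6 lines), against 0.193 ± 0.0120 (SD, n = 6) at 0.00061 µg/mL. The difference was 0.0787 ± 0.0324 (SD) and positive in 6 of 6 lines (exact two-sided sign-flip p = 0.03125, the smallest that 6 lines can give, and 0.0833 after adjustment over 4 such tests). After 12 h the high dose gave 0.973 ± 0.126 (SD, n = 5) and the low dose 0.201 ± 0.0209 (SD, n = 6). That difference of 0.772 ± 0.130 was positive in 5 of 5 lines (exact p = 0.0625, the smallest that 5 lines allow). From 2 to 12 h the response to the high dose grew by 0.697 ± 0.107 in 5 of 5 lines (exact p = 0.0625), and that to the low dose differed by 0.00757 ± 0.0299 and was larger in 4 of 6 lines (exact p = 0.5625). Without any single line the test at 2 h had 5 lines and could not go below 0.0625. A line had a median of 38 genes at least 2-fold higher and 40.5 lower at 2 h, and 1324 higher and 2885 lower at 12 h. At the low dose these medians were 4 and 3.5 at 2 h and 7 and 7 at 12 h. At 48 h the high dose gave 0.888 in U2932 and 1.40 in RIVA, and the low dose 0.191 ± 0.00591 (SD, n = 3).

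**Figure D2:**
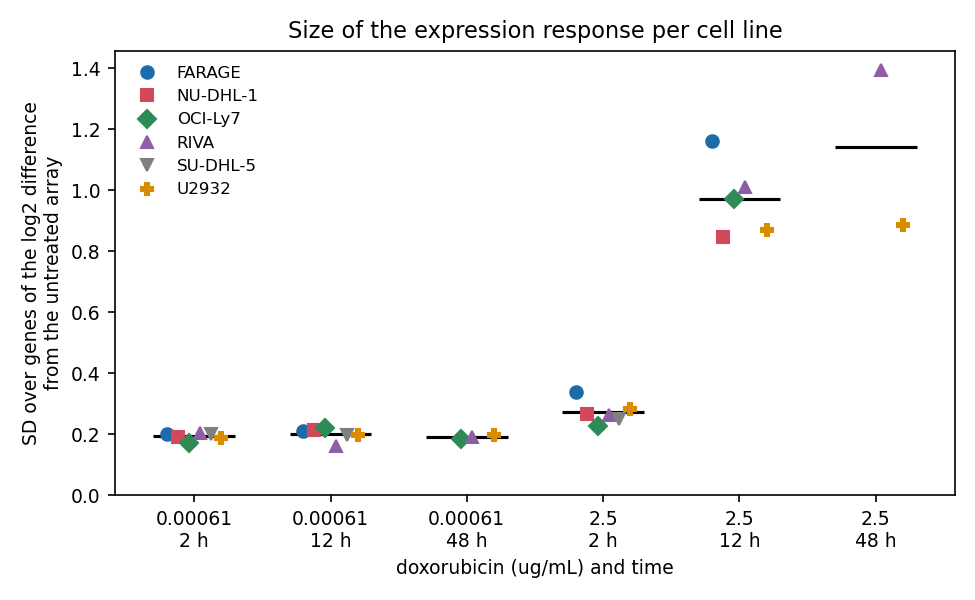
SD over genes of the log2 difference from the untreated array of the same line and time, per line (points) with the mean (bar), by dose and time. All lines lay between 0.846 and 1.16 at 2.5 µg/mL and 12 h, and between 0.163 and 0.221 at 0.00061 µg/mL and 12 h.

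After 2 h at 2.5 µg/mL, stress-induced immediate early genes led the rises. IER3, a stress-induced regulator of apoptosis, rose by 2.23 ± 0.19 (adjusted p = 3.45e-05, 0.90 to 2.94 across the 6 lines). The AP-1 subunit JUN rose by 2.00 ± 0.23 (adjusted p = 2.23e-04). Also higher were TNFRSF10D, a decoy receptor for TRAIL (1.75 ± 0.25), GADD45B, a DNA damage and stress gene (1.71 ± 0.34), the costimulatory ligand TNFSF9 (1.32 ± 0.16), the small MAF factor MAFF (1.30 ± 0.13), the MYC antagonist MXD1 (1.22 ± 0.10) and the transcriptional coregulator CITED2 (1.14 ± 0.17). NFKBID (1.09 ± 0.08), SERTAD1 (1.08 ± 0.08), ULBP2, a ligand of the natural killer receptor NKG2D (1.08 ± 0.20), and the MAP kinase phosphatase DUSP1 (1.02 ± 0.15) completed the 12 largest rises.

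The largest falls at 2 h included regulators of B cells and of transcription. TAGAP fell by 1.55 ± 0.29, PPP1R10, a nuclear targeting subunit of protein phosphatase 1, by 1.51 ± 0.12 (adjusted p = 2.50e-05), the G-protein regulator RGS1 by 1.46 ± 0.16 and the pseudokinase gene TRIB1 by 1.34 ± 0.19. The oncogene MYC decreased by 1.15 ± 0.21 (adjusted p = 0.00382), from -2.73 in FARAGE to -0.47. ID3, an inhibitor of E proteins, was at -1.14 ± 0.11, and the repressor gene BHLHE40 at -1.26 ± 0.17. The others of the 12 largest falls, KBTBD7 (-1.32), GTF2H2B (-1.31), LDLRAD4 (-1.24), ZNF594 (-1.11) and PDE4B (-1.11), were lower in 6 of 6 lines too. The anti-apoptotic gene BCL2 fell by 0.51 ± 0.11 (adjusted p = 0.0104).

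Of the single genes, CDKN1A, the cell cycle inhibitor p21, stood at 0.45 ± 0.18 (adjusted p = 0.148), from -0.27 in FARAGE to 1.74 in SU-DHL-5. MDM2, the ligase that degrades p53, was at -0.18 ± 0.10 (adjusted p = 0.311) and the death receptor FAS at 0.10 ± 0.19 (adjusted p = 0.814). Neither topoisomerase II gene passed the test, with TOP2A at -0.12 ± 0.07 and TOP2B at 0.02 ± 0.03. BCL6, a repressor of the germinal centre, was at -0.33 ± 0.16, MCL1 at 0.21 ± 0.09, the drug efflux pump ABCB1 at -0.15 ± 0.08, IRF4 at 0.03 ± 0.09 and PRDM1 at 0.04 ± 0.09 (adjusted p between 0.198 and 0.877).

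In all, 2057 of 19775 genes were called at 2 h, 796 higher and 1261 lower, and 18 and 14 of these were at least 2-fold. In simulated data of this comparison, with the noise of the low dose, 77% of genes changed by 0.5 were recovered. The count fell to 1368 without U2932, to 1004 with variances fitted without a trend, to 52 in a joint fit of all arrays, and to 0 without the line as a block. The joint fit borrows its error from all doses and times, and the fit without a block sets the change against differences between lines.

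By list, immediate early genes were higher at 2 h, with a median of 0.35, 10 of 28 higher, 2 lower and 16 not passing (13 and 2 adjusted over the list alone), and adjusted p = 0.00721 against other genes (adjusted p = 0.394 with an estimated correlation). KLF6 fell by 0.85 ± 0.07. The p53 targets had a median of 0.14, with 2 of 28 higher, 1 lower and 25 not passing (6 and 1 adjusted over the list alone), and adjusted p = 0.00984 (adjusted p = 0.509 with an estimated correlation). By line the median of the p53 target genes was 0.47 in SU-DHL-5 and from -0.04 to 0.13 in the others. The death receptor TNFRSF10B rose by 0.72 ± 0.12 and SESN2 by 0.52 ± 0.07, while the translesion polymerase POLH fell by 0.31 ± 0.09. Interferon response genes had a median of 0.07, with 6 of 27 higher and 1 lower (6 and 1 adjusted over the list alone), and adjusted p = 0.0327 (adjusted p = 0.351 with an estimated correlation). IRF7 rose by 0.90 ± 0.10 and IFIT5 fell by 0.56. Oxidative and iron response genes (median 0.09, 5 of 17 higher, 9 adjusted over the list alone) gave adjusted p = 0.0225 (adjusted p = 0.394 with an estimated correlation), with SOD2 up by 0.42 ± 0.07. Respiratory chain genes (median 0.07, 9 of 31 higher, 12 adjusted over the list alone) gave adjusted p = 0.00117 (adjusted p = 0.464 with an estimated correlation), with NDUFA2 up by 0.15 ± 0.03. Scaled to the poly-A controls, IRF7 was called at 0.60, SESN2 and SOD2 stood at 0.21 and 0.12 and were no longer called, and NDUFA2 turned to -0.16. These values rest on the mean of the controls, which at 2 h moved more than their median, and untreated arrays shifted by a like size. On that scale the medians were 0.04 for immediate early genes, -0.16 for p53 targets, -0.23 for interferon genes, -0.21 for oxidative and iron genes and -0.23 for the respiratory chain, against -0.28 for the median gene.

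The B-cell identity list was lower at 2 h, with a median of -0.08, 8 of 30 lower, 1 higher and 21 not passing (10 and 1 adjusted over the list alone), and adjusted p = 1.41e-04 (adjusted p = 0.255 with an estimated correlation). The B-lineage transcription factors IKZF3 (-0.48 ± 0.04), EBF1 (-0.38 ± 0.05), IKZF1 (-0.33 ± 0.04) and PAX5 (-0.28 ± 0.04) fell. Germinal centre markers (median -0.05, 3 of 17 lower, 3 adjusted over the list alone) gave adjusted p = 0.0288 (adjusted p = 0.389 with an estimated correlation), with GCSAM at -0.66 ± 0.07. Activated B-cell markers (median -0.13, 5 of 19 lower and 1 higher, 6 and 2 adjusted over the list alone) gave adjusted p = 0.00416 (adjusted p = 0.351 with an estimated correlation), with ETV6 at -0.46 and the kinase gene PIM2 at 0.36 (0.06 on the poly-A scale and no longer called).

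The lists of G2 and mitosis, DNA damage response, ZNF and histone genes were lower at 2 h as well. G2 and mitosis genes (median -0.07, 5 of 30 lower and 1 higher, 8 and 3 adjusted over the list alone) gave adjusted p = 1.12e-04 (adjusted p = 0.351 with an estimated correlation), and the mitotic kinesin KIF20A fell by 0.55 ± 0.06. DNA damage response genes (median -0.05, 5 of 27 lower, 7 adjusted over the list alone) gave adjusted p = 0.00117 (adjusted p = 0.351 with an estimated correlation), with the histone variant gene H2AX at -0.56 ± 0.04 and BARD1 at -0.41 ± 0.07. Of 466 ZNF genes, 87 were lower and 7 higher (101 and 10 adjusted over the list alone), with a median of -0.08 and adjusted p = 3.01e-07 (adjusted p = 0.351 with an estimated correlation). ZNF407 fell by 0.68 ± 0.07. Replication-dependent histones (median -0.06, 4 of 42 lower, 4 adjusted over the list alone) gave adjusted p = 0.0291 (adjusted p = 0.418 with an estimated correlation).

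The other lists did not pass at 2 h. Their medians were 0.05 for G1/S genes (3 higher and 3 lower, 11 and 4 adjusted over the list alone), -0.08 for the BCL2 family, -0.05 for NF-kB targets, 0.02 for heat shock, 0.04 for doxorubicin transport and targets, and 0.01 for ribosomal proteins (adjusted p between 0.297 and 0.757). Signs differed in 3 lists. The stress response list had a median of -0.02 and a mean of 0.05, ribosome biogenesis a median of 0.03 and a mean of -0.00269, and plasma cell genes a median of 0.01 with a downward test (adjusted p = 0.981, 0.815 and 0.843). Within the stress list DNAJB9 rose by 0.67 ± 0.06 and HERPUD1 fell by 0.59 ± 0.11.

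After 12 h at 2.5 µg/mL, the largest rises were in genes near or below the median level in untreated cells. ULBP2 rose by 4.64 ± 0.54 (adjusted p = 0.00198, 2.80 to 6.76 across the 5 lines). DLX2, a homeobox gene of the developing brain and jaw, rose from a mean of 3.87 to 8.43, by 4.55 ± 0.21 (adjusted p = 2.87e-04). TNFRSF10D (4.02 ± 0.53), the small Cajal body RNA gene SCARNA2 (4.02 ± 0.65), the stress factor ATF3 (3.86 ± 0.46), the zinc finger gene INSM2 (3.84 ± 0.51), smooth muscle actin ACTA2 (3.52 ± 0.34), the AP-1 subunit FOSB (3.49 ± 0.46), the Notch target HEY1 (3.39 ± 0.39), CAV1 of caveolae (3.32 ± 0.66) and RFPL3S (3.23 ± 0.28) were higher in 5 of 5 lines. EIF4A2 was at 3.61 ± 0.44, from a probe set that lay at 3.56 in untreated cells although the gene encodes an abundant translation factor.

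The largest falls at 12 h reached genes that were well expressed without the drug. BUB1B, a kinase of the mitotic checkpoint, fell by 4.00 ± 0.39 from a level of 11.4 (adjusted p = 0.00143, -5.65 to -2.83), and the mitotic motor KIF11 by 3.83 ± 0.54. The splicing kinase gene PRP4K fell by 4.31 ± 0.67, RFXAP, a regulator of MHC class II genes, by 4.30 ± 0.53, the Polycomb cofactor gene AEBP2 by 4.01 ± 0.58, MBTPS2, a protease that activates sterol and stress factors, by 3.96 ± 0.31 and the nuclear pore gene NUP98 by 3.95 ± 0.57. DIPK1A (-4.06), PET117 (-3.97), STAMBPL1 (-3.87), DENND6A (-3.84) and YEATS4 (-3.81) were lower in 5 of 5 lines too.

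Of the single genes at 12 h, MDM2 fell by 2.50 ± 0.61 (adjusted p = 0.0206), lower in 4 of 5 lines and at 0.80 in NU-DHL-1. TOP2A, the drug's target in dividing cells, fell by 0.82 ± 0.17 (adjusted p = 0.0114, 5 of 5 lines). The others did not pass: CDKN1A was at -0.26 ± 0.44 (-1.86 to 1.71), FAS at 0.72 ± 0.85 (-3.43 to 2.82), TOP2B at -0.35 ± 0.14, MYC at -1.22 ± 0.49, BCL2 at -0.65 ± 0.53, BCL6 at -1.09 ± 0.56, MCL1 at -1.25 ± 0.44, ABCB1 at 0.73 ± 0.28, IRF4 at -0.60 ± 0.50 and PRDM1 at 0.58 ± 0.20 (adjusted p between 0.0572 and 0.646).

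At 12 h, 6494 genes were called, 3591 higher and 2903 lower, and 623 and 2216 of these were at least 2-fold. In simulated data of this comparison 62% of genes changed by 0.5 were recovered. That share is for the noise of the low dose, which was smaller than the real one (median standard error 0.205 here against 0.0791). The count was 2367 without RIVA, 2588 without OCI-Ly7, 2702 without U2932, 4096 of genes above the median level alone, 4212 without the line as a block and 13100 in a joint fit of all arrays. Which direction held more genes was not stable. Lower genes outnumbered higher ones with arrays centred on their medians, with genes above the median level alone, without FARAGE, OCI-Ly7, RIVA or U2932, and on the scales of both sets of control transcripts. Of the genes higher at 2 h, 322 were also higher at 12 h (144.5 if the lists were independent) and 18 were lower. Of the genes lower at 2 h, 909 were lower at 12 h (185.1 if independent) and 2 were higher.

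**Figure D3:**
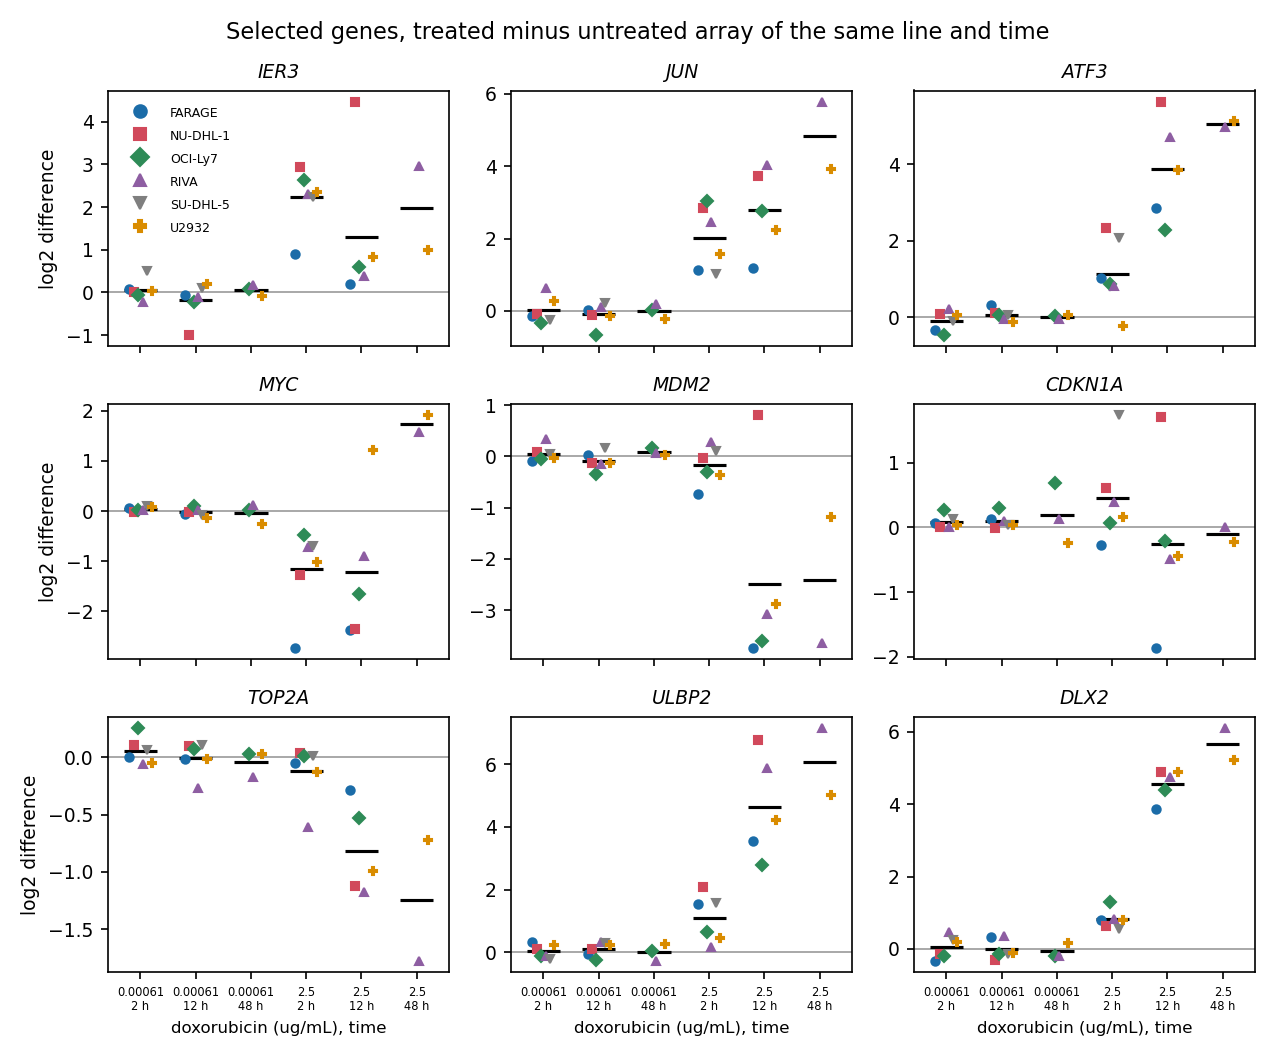
Log2 difference from the untreated array of the same line for 9 genes, by dose and time, with lines as points and their mean as a bar. ULBP2 and DLX2 reached means of 4.64 and 4.55 after 12 h at 2.5 µg/mL, and MYC was at -1.15 after 2 h.

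By list, G2 and mitosis genes were the most uniform at 12 h, with 22 of 30 lower, 0 higher and 8 not passing (23 lower adjusted over the list alone), and a median of -1.46 (adjusted p = 1.46e-14, adjusted p = 0.287 with an estimated correlation). Their medians per line lay between -2.06 in FARAGE and -1.14 in NU-DHL-1. The kinetochore motor CENPE fell by 3.32 ± 0.36, DLGAP5 by 2.44 ± 0.23 and the kinase AURKB by 2.09 ± 0.21. G1/S genes had 9 of 29 lower and 2 higher (11 and 3 adjusted over the list alone), with a median of -0.44 and adjusted p = 0.00364 (adjusted p = 0.584 with an estimated correlation). CDCA7 fell by 2.29 ± 0.28 and SLBP, the histone mRNA binding protein, by 2.29 ± 0.39. DNA damage response genes had 13 of 27 lower (15 lower and 1 higher adjusted over the list alone), with a median of -0.73 and adjusted p = 2.87e-07 (adjusted p = 0.287 with an estimated correlation). The checkpoint kinase CHEK2 fell by 2.21 ± 0.24, RAD50 by 2.47 ± 0.30, and TDP1, which removes topoisomerase adducts, by 2.50 ± 0.32.

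The B-cell programme was lower at 12 h. In the B-cell identity list 17 of 30 genes were lower, 2 higher and 11 not passing (19 and 2 adjusted over the list alone), with a median of -0.87 and adjusted p = 3.25e-08 (adjusted p = 0.287 with an estimated correlation). The adaptor gene BLNK fell by 3.33 ± 0.29, the transcription factor gene SPIB by 2.21 ± 0.27, IKZF3 by 2.09 ± 0.27 and the coactivator gene POU2AF1 by 1.87 ± 0.17. Germinal centre markers (7 of 17 lower and 1 higher, 7 and 1 adjusted over the list alone) had a median of -0.92 and adjusted p = 7.29e-04 (adjusted p = 0.356 with an estimated correlation), with GCSAM at -2.78 ± 0.50. Activated B-cell markers (5 of 19 lower and 2 higher, 5 and 2 adjusted over the list alone) had a median of -0.45 and adjusted p = 0.00625 (adjusted p = 0.356 with an estimated correlation). IL16 fell by 2.64 ± 0.28 and STAT3 rose by 1.11 ± 0.19, which turned to -0.68 when scaled to the poly-A controls.

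Ribosome biogenesis genes were lower at 12 h in 11 of 25 and higher in 0 (12 lower adjusted over the list alone), with a median of -0.59 and adjusted p = 3.32e-05 (adjusted p = 0.356 with an estimated correlation). The RNA polymerase I subunit POLR1B fell by 2.42 ± 0.23. The stress response list had 7 of 25 lower and 1 higher (7 and 1 adjusted over the list alone), a median of -0.30 and adjusted p = 0.0232 (adjusted p = 0.457 with an estimated correlation). Its core transcription factor ATF4 fell by 1.57 ± 0.27, its chaperone cofactor SDF2L1 by 2.00 ± 0.27 and HERPUD1 by 2.53 ± 0.52. ZNF genes had 152 of 466 lower and 23 higher (158 and 26 adjusted over the list alone), with a median of -0.43 and adjusted p = 1.01e-09 (adjusted p = 0.356 with an estimated correlation), with ZNF764 at -3.00.

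A few gene groups stood above the bulk at 12 h. The bulk itself differed by level. Genes not below the median level in untreated cells had line medians of -0.292 to -0.126, and those below it 0.150 to 0.467. The list tests took no account of level, so that the direction of a list may in part follow the level of its members. That was not tested. Interferon response genes had 12 of 27 higher and 0 lower (12 adjusted over the list alone), a median of 0.83 and adjusted p = 0.0172 (adjusted p = 0.651 with an estimated correlation). IRF7, the master regulator of interferon induction, rose by 2.66 ± 0.42, IFI6 by 2.39 ± 0.28 and IFIT3 by 1.43 ± 0.26. Medians of the type I interferon response genes per line were 2.68 in NU-DHL-1, 1.13 in U2932, 0.37 in FARAGE, 0.20 in RIVA and 0.16 in OCI-Ly7. Replication-dependent histone genes, whose mRNAs normally lack a poly-A tail, had 12 of 42 higher and 0 lower (11 adjusted over the list alone), a median of 0.65 and adjusted p = 7.29e-04 (adjusted p = 0.651 with an estimated correlation). Respiratory chain genes had 15 of 31 higher and 2 lower (17 and 2 adjusted over the list alone), a median of 0.34 and adjusted p = 0.0396 (adjusted p = 0.684 with an estimated correlation). Scaled to the poly-A controls these medians turned to -0.95, -1.13 and -1.44, against -1.59 for the median gene, and IRF7 was called at 0.87, while IFI6 stood at 0.61 and was no longer called and IFIT3 turned to -0.35.

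The remaining lists did not pass at 12 h. The p53 targets had a median of 0.31 (2 of 28 higher and 2 lower, 0 and 2 adjusted over the list alone, adjusted p = 0.949). Per line, the median of the p53 target genes ran from -0.40 in FARAGE to 1.03 in NU-DHL-1. Immediate early genes were at 0.40 (5 of 28 higher and 3 lower, adjusted p = 0.643), with JUN up by 2.79 ± 0.41 and JUND down at -2.42 ± 0.35. NF-kB targets were at -0.37 (3 higher and 2 lower, adjusted p = 0.114), the BCL2 family at -0.22, heat shock genes at -0.09, oxidative and iron genes at 0.32 (8 of 17 higher), plasma cell genes at -0.52, ribosomal proteins at 0.12 (10 of 57 higher and 2 lower) and doxorubicin transport and target genes at 0.25 (adjusted p between 0.356 and 0.395). SOD2, the mitochondrial superoxide dismutase, rose by 2.13 ± 0.24 and the anthracycline reductase gene CBR3 by 1.61 ± 0.26. Scaled to the poly-A controls SOD2 stood at 0.35 and was no longer called, and CBR3 turned to -0.18.

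**Figure D4:**
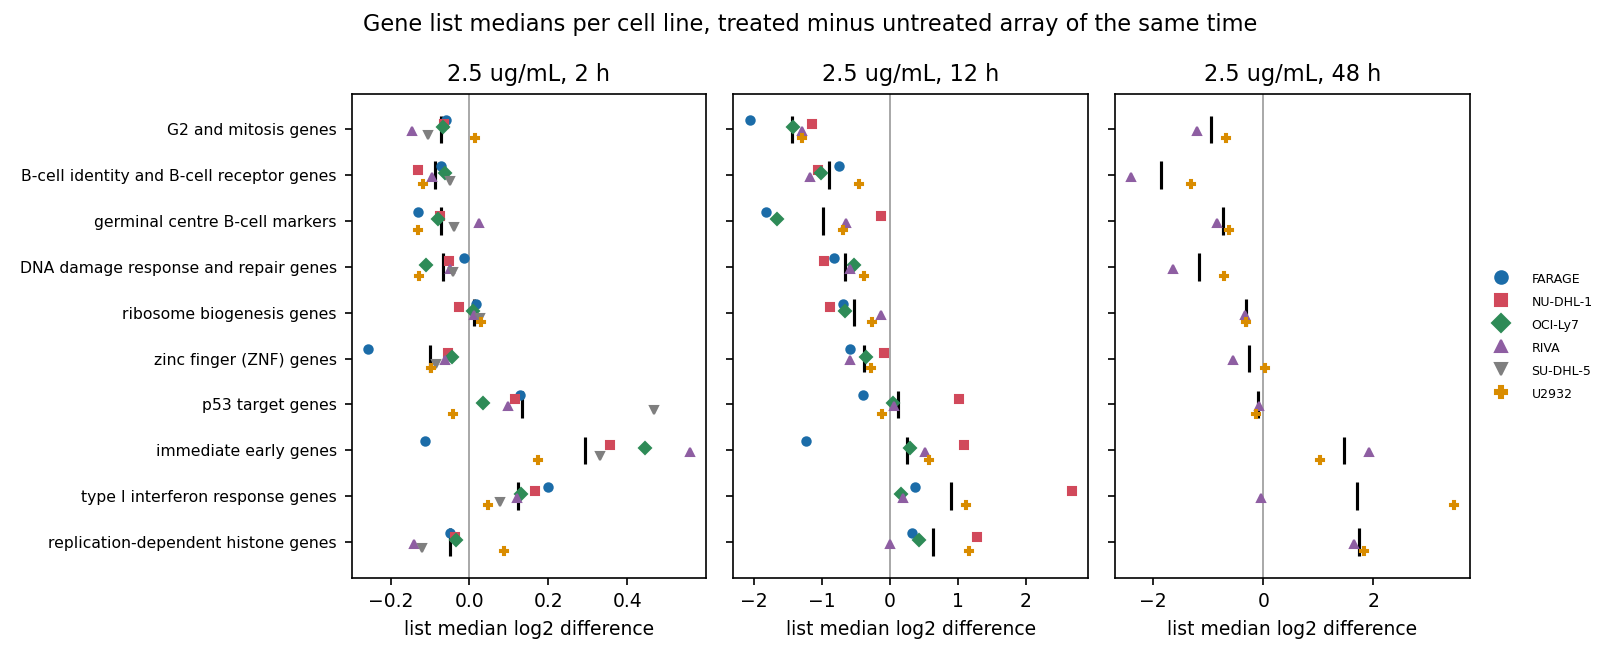
Median log2 difference of 10 gene lists per line (points), with the mean over lines (bar), after 2, 12 and 48 h at 2.5 µg/mL. G2 and mitosis genes lay at medians of -0.07, -1.46 and -0.92, and histone genes at -0.06, 0.65 and 1.79, with the last 2 turning to -1.13 and -1.45 when arrays were scaled to the poly-A controls.

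Gene length went with the direction of change at 2.5 µg/mL. For 19738 of the 19775 genes (99.8%) a span on assembly GRCh38.p14 was found. They were put in 5 equal groups with median spans of 3.30, 11.2, 24.7, 52.7 and 154 kb. The groups also differed in level, with medians of 4.97, 5.71, 6.48, 6.81 and 5.60 in untreated cells. The shares below were not adjusted for level. At 2 h 3.42% of the shortest and 12.4% of the longest group were lower, and 5.24% and 0.659% higher. At 12 h the shares lower were 6.69%, 10.6%, 15.6%, 20.5% and 20.1%, and the shares higher went from 26.3% in the shortest to 12.3% in the longest group. At 48 h the shares lower were 3.12% and 15.0%, and those higher 10.6% and 2.41%. Across genes, which are not independent replicates, the Spearman correlation of span with the log2 difference at 12 h was between -0.232 in U2932 and -0.0876 in NU-DHL-1 at the high dose, and between -0.0608 and 0.0156 in the 6 lines at the low dose.

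**Figure D5:**
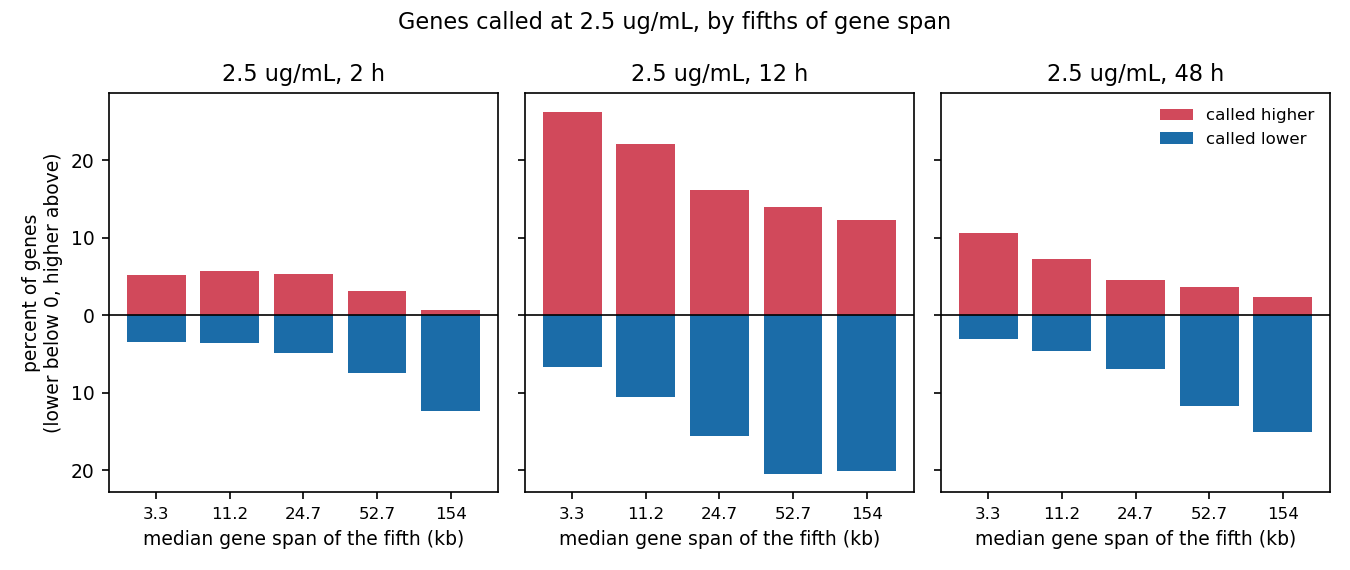
Percent of genes called higher and lower in 5 equal groups of genes by span in kb (group medians 3.30 to 154 kb), after 2, 12 and 48 h at 2.5 µg/mL. The share lower rose from 6.69% to 20.1% at 12 h from the shortest to the longest group, all relative to the bulk of the genes. The groups also differed in median untreated level (4.97 in the shortest, 5.60 in the longest and up to 6.81 between), for which the shares were not adjusted.

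Markers of other cell types were read beside these groups. At 12 h, 9 of 23 markers were called higher and 0 lower: 2 of 5 T cell, 4 of 6 myeloid, 1 of 2 erythroid, 0 of 5 fibroblast and 2 of 5 epithelial. Their medians were 0.56, 0.49, 0.42, 0.26 and 0.43. CD14 rose by 1.69 from a level of 4.02, while the abundant myeloid transcript LYZ differed by 0.00737 within lines. Its means were 3.54 over 6 untreated and 3.56 over 5 treated lines. Only HBB, DCN and COL1A1 of the 23 lay above the median gene's level of 5.83 in untreated cells. At 2 h the medians were 0.05, 0.09, 0.17, 0.03 and 0.10, with 1 erythroid marker higher. The 3'-to-5' difference of actin probe sets, a sign of RNA quality, was larger on the treated arrays at 12 h by 0.0913 to 0.730.

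At 48 h the high dose was measured in RIVA and U2932 only, and the largest rises again came from genes at or below the median level without the drug. SERPINB5, an epithelial serpin, rose by 7.03 ± 0.50 (adjusted p = 4.51e-05, 6.78 and 7.28 in the lines). SCARNA2 rose by 7.04 ± 0.53, the nuclear receptor gene NR2F1 by 6.67 ± 0.52, the homeobox gene HOXB7 by 6.30 ± 0.55, INSM2 by 6.10 ± 0.65, ULBP2 by 6.07 ± 0.61 and FOSB by 5.84 ± 0.75. EIF4A2 was at 7.05 ± 0.51 from the same dim probe set. ZNF804A fell by 5.43 ± 0.57 from a level of 11.0, and ANKRD36BP2 (-4.43 ± 0.69), the microRNA gene MIR146A (-4.33 ± 0.73), RAPGEF5 (-4.16 ± 0.54), the inhibitory receptor gene PVRIG (-4.10 ± 0.49), PRP4K (-4.01 ± 0.79), NLRP11 (-4.01 ± 0.57) and the ubiquitin conjugase gene UBE2E2 (-3.98 ± 0.58) fell as well.

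MYC, lower at 2 h, was higher at 48 h by 1.75 ± 0.48 (adjusted p = 0.0307, both lines) and stood at -1.49 when scaled to the poly-A controls. MDM2 fell by 2.41 ± 0.63 (adjusted p = 0.0252), TOP2B by 2.07 ± 0.44 (adjusted p = 0.0119) and MCL1 by 1.16 ± 0.31 (adjusted p = 0.0283). ABCB1 rose by 1.34 ± 0.38 (adjusted p = 0.0340) and stood at -1.90 on the poly-A scale. Values that did not pass were 2.10 ± 0.85 for FAS, -1.25 ± 0.40 for TOP2A, -0.11 ± 0.50 for CDKN1A, -0.53 ± 0.28 for BCL2, -0.63 ± 0.36 for BCL6, -1.05 ± 0.41 for IRF4 and 0.52 ± 0.47 for PRDM1.

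At 48 h 2757 genes were called, 1119 higher and 1638 lower, of which 1013 and 1633 were at least 2-fold. Which direction held more genes was not stable here either. Higher genes were the more in a joint fit of all arrays (6269 higher and 4798 lower) and without the line as a block (22 and 1). With 2 lines the main fit had 1 residual degree of freedom. In simulated data with the smaller noise of the low dose it recovered 7% of genes changed by 1. The count was 9 with variances fitted without a trend, 23 without the line as a block, 987 against the untreated array at 0 h and 11067 in a joint fit of all arrays, where it was 5863 without RIVA and 11233 without U2932. With arrays scaled to the hybridization controls 5409 genes were called, 115 higher and 5294 lower. Genes called at 12 and 48 h shared 690 rises (203.2 if independent) and 1277 falls (240.5 if independent), and 0 genes turned.

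By list, histone genes were the clearest group at 48 h. Of 42 genes 27 were higher and 0 lower (33 adjusted over the list alone), with a median of 1.79 and adjusted p = 5.95e-15 (adjusted p = 0.608 with an estimated correlation). H3C2 rose by 5.20 ± 0.52, H2AC8 by 5.03 ± 0.54 and H2BC21 by 4.36 ± 0.53. Interferon response genes had 11 of 27 higher and 0 lower (16 adjusted over the list alone), with a median of 2.12 and adjusted p = 6.54e-05 (adjusted p = 0.703 with an estimated correlation). IFI27 rose by 5.51 ± 0.80 and IFI6 by 5.01 ± 0.56. Immediate early genes had 12 of 28 higher and 1 lower (20 and 2 adjusted over the list alone), with a median of 1.57 and adjusted p = 5.87e-07 (adjusted p = 0.608 with an estimated correlation). ATF3 rose by 5.05 ± 0.50 and JUN by 4.85 ± 0.60. On the poly-A scale these medians turned to -1.45, -1.12 and -1.67, against -3.07 for the median gene, and the named members stood above 0, of which H2BC21 (1.12) and IFI27 (2.27) were no longer called.

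Lower at 48 h were B-cell identity genes, with 18 of 30 lower and 1 higher (20 and 2 adjusted over the list alone), a median of -1.75 and adjusted p = 3.81e-08 (adjusted p = 0.608 with an estimated correlation). POU2F2 fell by 3.45, BLNK by 3.43 and POU2AF1 by 2.77, while CD74, the invariant chain of MHC class II, rose by 2.39 ± 0.37 (-0.85 on the poly-A scale). G2 and mitosis genes (8 of 30 lower, 11 adjusted over the list alone, median -0.92) gave adjusted p = 9.87e-06, DNA damage response genes (7 of 27 lower, 12 adjusted over the list alone, median -1.11) adjusted p = 1.11e-05, NF-kB targets (8 of 24 lower and 1 higher, 9 and 4 adjusted over the list alone, median -0.86) adjusted p = 0.0184, and germinal centre markers (6 of 17 lower and 1 higher, 7 and 2 adjusted over the list alone, median -0.63) adjusted p = 0.0198. Activated B-cell markers (4 of 19 lower, 5 and 1 higher adjusted over the list alone, median -1.02) gave adjusted p = 1.17e-04, plasma cell genes (5 of 13 lower and 1 higher, 6 and 1 adjusted over the list alone, median -1.21) adjusted p = 0.00327, and the BCL2 family (2 of 15 lower, 3 adjusted over the list alone, median -0.53) adjusted p = 0.0261. Each of these 7 lists had adjusted p = 0.608 with an estimated correlation. At 48 h that test had 1 degree of freedom and could hardly pass, so that it decides nothing for any list here. G1/S genes (4 of 29 lower, 4 and 1 higher adjusted over the list alone, median -0.59, adjusted p = 0.0112) and ZNF genes (52 of 466 lower and 13 higher, 52 and 13 adjusted over the list alone, median -0.25, adjusted p = 0.00225) had adjusted p = 0.703 with an estimated correlation. On the poly-A scale the tests of the G1/S, NF-kB and ZNF lists against other genes did not pass (adjusted p = 0.970, 0.616 and 0.571), although their medians stayed below that of the median gene (-3.83, -4.10 and -3.49 against -3.07).

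The other lists did not pass at 48 h, with medians of -0.10 for p53 targets, -0.33 for the stress response, 0.08 for oxidative and iron genes, -0.21 for ribosome biogenesis, -0.09 for the respiratory chain, -0.01 for ribosomal proteins and 0.27 for doxorubicin transport and targets (adjusted p between 0.0621 and 0.764). Heat shock genes had a median of -0.11 and a mean of 0.06 (adjusted p = 0.658). Among the p53 targets the kinase gene PLK2 rose by 4.03 ± 0.90 (0.79 on the poly-A scale and no longer called) and RRM2B, a p53-induced subunit of ribonucleotide reductase, fell by 2.50 ± 0.55. The medians of the markers of other cell types were 0.71, 0.58, 0.30, 0.49 and 0.33 in the order above, with 3 of 23 higher and CD14 at 3.36. The actin 3'-to-5' difference was larger by 0.392 and 1.05.

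The low dose of 0.00061 µg/mL left 0 genes called by limma at 2, 12 and 48 h, with 809, 1481 and 1465 genes at an unadjusted p below 0.05. At 2 h the smallest p-values belonged to ARPC3 (-0.14 ± 0.03), ERGIC1 (0.21 ± 0.04) and AGBL2 (-0.38 ± 0.09), all at adjusted p = 0.999. At 12 h they belonged to LOC105369477 (-0.49 ± 0.09), GDPGP1 (-0.47 ± 0.09) and LMF2 (-0.23 ± 0.05), at adjusted p of 0.554 to 0.622. At 48 h (n = 3 lines) they belonged to UBN1 (-0.39 ± 0.07), WDR43 (0.36 ± 0.06) and PTP4A1 (0.32 ± 0.06), at adjusted p of 0.180 to 0.238. CDKN1A stood at 0.09 ± 0.04 at 2 h, 0.10 ± 0.04 at 12 h and 0.19 ± 0.11 at 48 h (adjusted p = 0.999, 0.640 and 0.730), and MDM2 at 0.05 ± 0.04, -0.10 ± 0.05 and 0.09 ± 0.05.

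In simulated data, all with the noise of the comparison at 12 h, these comparisons recovered 77%, 83% and 24% of genes changed by 0.5. At 48 h 14 genes were called without RIVA and 158 without U2932. Against the untreated array at 0 h, 281 genes were called at 2 h and 5 at 12 h. Scaled to the poly-A controls, 6046 were called at 12 h, 6044 of them higher, and 4 at 48 h, which repeats a single shift per array. The genes that rose or fell at least 2-fold after 12 h at the high dose had medians of -0.03 to 0.03 and 0.02 to 0.08 after 48 h at the low dose in OCI-Ly7, RIVA and U2932. No list passed at 2 h. At 12 h ZNF genes had a median of -0.02 (adjusted p = 0.01002, adjusted p = 0.721 with an estimated correlation). At 48 h G2 and mitosis genes had a median of 0.10 (7 higher and 0 lower adjusted over the list alone, adjusted p = 1.42e-05) and ribosome biogenesis genes a median of 0.08 (2 higher, adjusted p = 8.33e-04), each with adjusted p = 0.903 with an estimated correlation. Against the untreated array at 0 h both lists turned, to medians of -0.06 and -0.76. That control adds 48 h of culture, in which ribosome biogenesis genes fell without the drug (below), so that these medians mix culture time with dose. None of the 23 markers of other cell types was called at 12 or 48 h.

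Compared directly, the doses differed in 2019 genes at 2 h (834 higher and 1185 lower at the high dose), 5762 at 12 h (2927 and 2835) and 3671 at 48 h (1455 and 2216, 2 lines). At 12 h lower genes were the more with arrays centred on their medians (1502 higher and 3063 lower) and on the poly-A scale (21 and 19360). The count at 48 h was 23 without the line as a block and 1541 without a variance trend. At 2 h IER3 (2.17 ± 0.20) and JUN (1.99 ± 0.24) were higher and PPP1R10 (-1.51 ± 0.11) and TAGAP (-1.49) lower. At 12 h ULBP2 (4.57 ± 0.50), DLX2 (4.52 ± 0.26) and the Notch ligand JAG1 (3.36) were higher and PRP4K (-4.37 ± 0.66), DIPK1A (-4.20 ± 0.49) and BUB1B (-4.02) lower. At 48 h SERPINB5 (7.01 ± 0.57) and NR2F1 (6.85 ± 0.56) were higher and ZNF804A (-5.44 ± 0.60) lower. G2 and mitosis genes were lower at 12 h by a median of -1.48 (adjusted p = 6.87e-15, adjusted p = 0.277 with an estimated correlation), and histone genes higher at 48 h by 1.77 (adjusted p = 1.01e-15, adjusted p = 0.595 with an estimated correlation). The count at 2 h was 45 in a joint fit of all arrays and 0 without the line as a block. That at 12 h was 2138 without RIVA, 2531 without OCI-Ly7 and 2598 without U2932, and that at 48 h, in a joint fit of all arrays, 6063 without RIVA and 11600 without U2932.

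Whether the effect of the high dose changed with time was tested within lines. From 2 to 12 h it changed in 4290 genes, upward in 1799 and downward in 2491 (5 lines). DLX2 (3.68 ± 0.25), ULBP2 (3.66 ± 0.51), SCARNA2 (3.49), INSM2 (3.44), EIF4A2 (3.35), RFPL3S (3.30), CAV1 (3.29) and ACTA2 (3.29) gained most. PRP4K (-3.89 ± 0.67), MBTPS2 (-3.81 ± 0.32), KIF11 (-3.66), PET117 (-3.65), YEATS4 (-3.62), RFXAP (-3.62), DCAF16 (-3.59) and DENND6A (-3.59) lost most. The count was 1426 without RIVA, 1723 without OCI-Ly7 and 1852 without U2932. From 12 to 48 h (RIVA and U2932) the effect changed in 35 genes, upward in 26 and downward in 9, among them SERPINB5 (4.48 ± 0.44), the histone gene H3C2 (3.77 ± 0.51), GADD45G (3.37) and ID1 (3.32) upward and LRBA (-2.89 ± 0.48), MYO1D (-2.61) and STX8 (-2.56) downward. This count was 0 with the mean of all probe sets, 0 among genes above the median level, 107 with arrays centred on their medians, 1 with variances fitted without a trend, and, in a joint fit of all arrays, 968 without RIVA and 5258 without U2932.

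Time in culture without the drug was the background of every exposure. At 2 h against 0 h 123 genes were called, 34 higher and 89 lower, and 0 reached 2-fold. CIRBP, a cold-inducible RNA-binding protein, was higher by 0.42 ± 0.03 (adjusted p = 4.82e-05), CMIP by 0.55 ± 0.10 and the cell cycle factor E2F1 by 0.42 ± 0.07, and RFX3 (-0.59 ± 0.07) and the co-chaperone gene CHORDC1 (-0.47 ± 0.04) were lower. The count was 28 without RIVA, 27 without FARAGE, 20 without NU-DHL-1, 20 without U2932 and 15 without SU-DHL-5. It was also 9 with the mean of all probe sets and 0 with variances fitted without a trend. Scaled to the poly-A controls, 1136 of 1137 called genes were higher at 2 h and 1036 of 1037 at 12 h, which repeats a single shift per array. At 12 h against 0 h 3 genes were higher, NCAPD2 of the condensin complex (0.37 ± 0.05), the fatty acid desaturase gene SCD (0.34 ± 0.04) and the sterol sensor gene INSIG1 (0.33 ± 0.05), and 0 were left without FARAGE, NU-DHL-1, OCI-Ly7 or RIVA. At 48 h against 0 h (3 lines) limma called 0 genes, with 2552 at an unadjusted p below 0.05, and 217 without U2932. LINC01857 (1.78 ± 0.18), LOC100996740 (1.25) and MRNIP-DT (1.14) had the smallest p-values there (adjusted p of 0.203 to 0.297).

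By list, culture without the drug gave medians of at most 0.16 in size among lists that passed at 2 and 12 h, such as immediate early genes at 2 h (0.16, 11 of 28 higher adjusted over the list alone, adjusted p = 1.08e-05, adjusted p = 0.412 with an estimated correlation) and ribosome biogenesis at 12 h (-0.13, 13 of 25 lower adjusted over the list alone, adjusted p = 7.26e-10, adjusted p = 0.454 with an estimated correlation). At 48 h ribosome biogenesis (-0.83, 23 of 25 lower adjusted over the list alone, adjusted p = 5.18e-21), heat shock (-0.84, 10 of 15 lower, adjusted p = 2.22e-08) and oxidative and iron genes (-0.51, 9 of 17 lower, adjusted p = 1.08e-07) lay lowest. The adjusted p was 0.582 with an estimated correlation for each.

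The lines sampled at 48 h (OCI-Ly7, RIVA and U2932) were compared with the other lines, a split that the labels give. No gene was called by limma for a different effect of the high dose at 2 h or at 12 h, with 903 and 947 genes at an unadjusted p below 0.05. The smallest p-values were those of ULBP2 (-1.30 ± 0.21), RNF144B (-0.65) and GADD45A (-1.33) at 2 h and of CLTRN (3.10), C16orf54 (4.18) and ZNF215 (-3.64) at 12 h (adjusted p from 0.195 to 0.468). By list, 2 passed at 2 h and 8 at 12 h with the preset correlation and 0 with an estimated one. The effect on p53 target genes was lower in the lines sampled at 48 h, by -0.24 at 2 h (adjusted p = 3.54e-04, adjusted p = 0.949 with an estimated correlation) and -0.45 at 12 h (adjusted p = 0.00200, adjusted p = 0.783 with an estimated correlation). This was not shared by the lines: at 2 h SU-DHL-5 stood at 0.47 and the others from -0.04 to 0.13, and at 12 h the lines without 48 h arrays were NU-DHL-1 at 1.03 and FARAGE at -0.40, the lowest of all. In simulated data of the comparison at 2 h, with the noise of the low dose, 47% of genes changed by 1 were recovered. Without OCI-Ly7 2 genes were called at 2 h, and at 12 h 18 without FARAGE and 1 without RIVA.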

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

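The tests of the control transcripts and the scaling of arrays to them were chosen after their result was seen. So was the rule that the bound for gene length counted only beyond 1 bootstrap standard error, and so were the tests of all genes below the median level. All other tests in this part were set before their own result. The test of RNA integrity for gene length chose FARAGE and U2932 by their actin differences, which had been seen by then. Whether the patterns of gene length and of dim genes had also been seen is not recorded.

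The control transcripts, which no comparison used, were brighter on the arrays at 2.5 µg/mL, on average by 1.87 at 12 h and 3.25 at 48 h on the log2 scale. The smallest poly-A difference of the 7 pairs was 1.41 against at most 0.247 among the 15 pairs at the low dose, and the smallest hybridization difference 0.508 against 0.177, as needed if less human target on an array was lifted by the normalization. Loss of RNA integrity as the cause is argued against by 14 untreated and low-dose arrays with an actin 3'-to-5' difference above 1.5 (up to 2.71), on which the poly-A controls lay no higher than -0.235 from the median of all untreated and low-dose arrays. The poly-A controls exceeded hybridization controls of like brightness by at least 0.486 in the 7 pairs and by at most 0.232 at the low dose, which is consistent with less polyadenylated RNA per amount of total RNA. A candidate explanation is a lower messenger RNA content of cells at the high dose, but the labels do not say how controls were added or how many cells were harvested, so this stays a hypothesis.

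Longer genes were lower at 2.5 µg/mL and 12 h. The bound set in advance, a rank correlation under -0.1 in every line, was not met: it was -0.0876 in NU-DHL-1 (bootstrap SE 0.00657, 200 resamples), so that an effect of exposure of that size in every line is argued against, although 4 of 5 lines lay under the bound and 5 of 5 lay lower than at the low dose (lowest -0.0608). Loss of RNA integrity as the cause is argued against by the values of FARAGE and U2932, the lines with the smallest shift in the actin difference, which were -0.168 and -0.232. Within 5 groups of genes by untreated level the median correlation was -0.0816 in NU-DHL-1 and between -0.188 and -0.134 in the other 4 lines, so that lifted dim genes and exposure cannot be told apart for NU-DHL-1. An effect of exposure that is smaller in NU-DHL-1 than in the other 4 lines stays open as a hypothesis, and why length would matter was not tested.

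Genes below the median level in untreated cells rose at 2.5 µg/mL and 12 h, by medians of 0.150 to 0.467 over all 10024 of them in the 5 lines, against at most 0.0563 at the low dose, so that a lift of dim genes by the normalization may be the cause. Of the 2538 called higher, 63 (2.48%) stayed above 0 when scaled to the poly-A controls, so that a rise only against a falling bulk may account for the others as well. The 14 genes picked in FARAGE and RIVA alone for rises of at least 2, among them ATF3, ULBP2, DLX2, CAV1 and the Notch ligand genes JAG1 and DLL1, rose in the lines not used to pick them by medians of 3.74 in NU-DHL-1, 2.10 in OCI-Ly7 and 3.73 in U2932, at least 1.19 above a bound from the 10024 genes (median plus 1 SD), and by 1.20, 0.796 and 2.19 when scaled to the poly-A controls. Picked for large rises, 14 of 2538 genes decide neither explanation for the rest, so that the bounds set on them in advance were the wrong test and both explanations stay open. The test for RNA from other cell types could not decide, with a median of 0.487 for its 23 markers at 48 h and 9 of them called higher at 12 h. All but HBB, DCN and COL1A1 of them lay below the median level in untreated cells, so that they may share the lift of dim genes. The labels name cultured lines only. Within lines LYZ, abundant in myeloid cells, differed by 0.00737 at 12 h and CD14 by 1.69.

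Whether chance can be excluded for the counts of genes was tested with other splits of the same arrays, most of which part fewer of the pairs of a line, and with swaps of the treatment within lines, which part every pair as the real split does. At 2 h and 2.5 µg/mL the real count was the largest in both. Against untreated cells this was 1 of 100 splits (2057 genes against at most 426) and 1 of 32 swaps (against at most 1). Against the low dose it was 1 of 100 (2019 against 512) and 1 of 32 (against 1). The other splits, and the swaps other than the real one, leave the effect of the drug in the error. Low counts there do not by themselves exclude chance. For the swaps, 1 of 32 is the smallest share that 6 lines can give and was not adjusted over the comparisons, so that chance is not called excluded. At 12 h the real count was the largest of the splits, against untreated cells (1 of 100, 6494 against 18) and against the low dose (1 of 100, 5762 against 16). With the effect of the drug left in the error of the other splits, this does not exclude chance either. The 16 swaps were too few for a share under 0.05 (6494 and 5762, against at most 0 in each). For the untreated change the splits and the swaps differed. By the splits chance cannot be excluded at 2 h (6 of 100, 123 against 768) or 12 h (9 of 100, 3 against 51). By the swaps the share was 1 of 32 at 2 h (123 against 0) and 1 of 32 at 12 h (3 against 1). That is again the smallest share possible and was not adjusted, so that chance is not called excluded for these counts. Why some splits called several times the real count was not tested. At the low dose limma called 0 genes (809, 1481 and 1465 at an unadjusted p below 0.05 at 2, 12 and 48 h), and since any count reaches 0 the splits decide nothing there (100 of 100 at 2 h, highest 5, and 100 of 100 at 12 h, highest 10). For the same reason they decide nothing, and besides were too few, at the low dose at 48 h (10 of 10, 0 genes against 4), for the untreated change at 48 h (10 of 10, 0 against 19) and for lines with against without 48 h arrays at 2 h (10 of 10, 0 against 3). They were too few for the change from 2 to 12 h (1 of 16 turnings of signs, 4290 against 0). The counts of 0 for the untreated change at 48 h and for the lines at 2 h, both from limma, stood beside 2552 and 903 genes at an unadjusted p below 0.05.

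The effect of 2.5 µg/mL differed between 12 and 2 h in 4290 genes and between 48 and 12 h in 35. It also differed between 12 and 2 h in 11 lists. None of these lists passed with an estimated correlation, where the adjusted p was 0.287 or higher. The medians of the differences were -1.38 for G2 and mitosis, -0.42 for G1/S, -0.66 for DNA damage response, 0.89 for interferon response, -0.51 for the unfolded protein and integrated stress response, -0.81 for B-cell identity, -0.79 for germinal centre markers, -0.46 for activated B-cell markers, -0.50 for ribosome biogenesis, -0.33 for ZNF genes and 0.77 for histones. Scaled to the poly-A controls, the interferon and histone medians were not higher than untreated at either time (-0.23 and -0.95 for interferon, -0.36 and -1.13 for histones at 2 and 12 h).

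A single line stood far from the others in 8 of 94 groups tested, and chance gives about 1 in 20. The values are as deposited, without scaling to controls. SU-DHL-5 had the highest p53 median at 2 h, 0.47 against -0.04 to 0.13. NU-DHL-1 had the lowest ribosome biogenesis median at 2 h, -0.03 (-0.0269) against 0.00982 to 0.0284, and the lowest ribosomal protein median at 12 h, 0.0144 against 0.12 to 0.16. FARAGE had the lowest ZNF median at 2 h, -0.26 against -0.10 to -0.04, the smallest rise of IER3, 0.90 against 2.24 to 2.94, and the largest fall of MYC, -2.73 against -1.28 to -0.47. MAFF rose most in RIVA, 2.23 against 0.88 to 1.28, and MXD1 most in OCI-Ly7, 1.85 against 0.89 to 1.18.

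Probe sets with no listed gene, outside all comparisons, also changed in the values as deposited. After 12 h at 2.5 µg/mL 2324 of 11721 were called (19.8%, against 24.7% of all probe sets), 1477 higher and 847 lower, with a largest rise of 4.04.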

How the results depend on the processing

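Scaling to control transcripts was chosen after seeing the data, and all other settings in advance. Where a cause is not named, the cause was not tested. Of the leave-one-line-out counts 43 stayed within 1.5 times or on the same side and 31 moved. Counts within 1.5 times, or on the same side, and counts that moved were 14 and 3 with arrays centred on their medians, 13 and 3 with genes above the median level, 13 and 4 with the mean of all probe sets, 9 and 7 without a variance trend, 9 and 7 with a 2-fold minimum, 4 and 3 against 0 h, 4 and 8 without the block, 3 and 9 in the joint fit and 2 and 13 on the poly-A scale. With 5 lines or fewer the test of the size of the response could not reach 0.05, so it is left out of these tallies. None of the 24 largest rises and falls named at 2 h, the 24 at 12 h and the 16 at 48 h at 2.5 µg/mL reversed under the settings run on them. On the poly-A scale, which lowered every difference alike, the falls could not reverse. Other named rises turned negative on the poly-A scale, such as STAT3 (-0.68), CBR3 (-0.18) and IFIT3 (-0.35) at 12 h, and MYC (-1.49), ABCB1 (-1.90) and CD74 (-0.85) at 48 h. NDUFA2 at 2 h (-0.16) did so too, but with the mean of the controls, which at that time moved more than their median. At 2 h 24 of these 24 genes lost their call without the block and 11 in the joint fit. At 12 h 1 did without the block, and at 48 h 13 of 16 did without the block, 11 without the trend and 2 with the mean of all probe sets. Of the list tests against untreated cells of the same time, at either dose, 40 passed with the preset correlation and 0 with an estimated one. At 48 h the latter had 1 degree of freedom at the high dose and 2 at the low dose. It could hardly pass there, so that its failure decides nothing at that time. Signal over background limits the dim genes: with genes above the median level alone, 17 of the 24 named at 12 h and 10 of the 16 at 48 h were tested.

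Below, H stands for 2.5 µg/mL against untreated, L for 0.00061 µg/mL against untreated, D for 2.5 against 0.00061 µg/mL, U for untreated against 0 h and T for a change of the effect of 2.5 µg/mL with time, each with its time.

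Genes called without a variance trend were 1004 (H 2 h), 9 (H 48 h), 1012 (D 2 h), 1541 (D 48 h), 0 (U 2 h), 0 (U 12 h) and 1 (T 12 to 48 h).

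In the joint fit of all 49 arrays, which pools the error over all doses and times, they were 52 (H 2 h), 13100 (H 12 h), 11067 (H 48 h), 45 (D 2 h), 12462 (D 12 h), 11440 (D 48 h), 0 (U 2 h), 0 (U 12 h) and 945 (U 48 h).

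With no block for the line, which adds the differences between lines to the error, they were 0 (H 2 h), 4212 (H 12 h), 23 (H 48 h), 0 (D 2 h), 3731 (D 12 h), 23 (D 48 h), 0 (U 2 h) and 0 (U 12 h).

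Against the untreated array at 0 h they were 987 (H 48 h), 281 (L 2 h) and 5 (L 12 h). With this control the medians of G2 and mitosis genes and of ribosome biogenesis genes at L 48 h turned to -0.0612 (adjusted p = 0.0511) and -0.756 (adjusted p = 2.96e-19). These values include the change over 48 h of culture, in which ribosome biogenesis genes also fell without the drug.

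Scaled to the poly-A controls, which moves every gene of an array alike, they were 7600 (H 2 h), 19138 (H 12 h), 19264 (H 48 h), 6046 (L 12 h), 4 (L 48 h), 6784 (D 2 h), 19381 (D 12 h), 19273 (D 48 h), 1137 (U 2 h), 1037 (U 12 h), 6221 (U 48 h), 18229 (T 2 to 12 h) and 17841 (T 12 to 48 h). The tests of G1/S genes (median -3.83), NF-kB targets (-4.10) and ZNF genes (-3.49) at H 48 h against other genes did not pass (adjusted p = 0.970, 0.616 and 0.571). The sign of the test turned, while the medians stayed below that of the median gene (-3.07) by the same distance as before scaling. Scaled to the hybridization controls the count at H 48 h was 5409, and the median gene stood at -1.28. Turns below 0 on the poly-A scale therefore depend on the choice of control.

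With a 2-fold minimum, which can only remove genes, they were 32 (H 2 h), 2839 (H 12 h), 33 (D 2 h), 2773 (D 12 h), 0 (U 2 h), 0 (U 12 h) and 2333 (T 2 to 12 h).

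With the mean of all probe sets they were 1844 (D 48 h), 9 (U 2 h), 0 (U 12 h) and 0 (T 12 to 48 h). Among genes above the median level they were 4096 (H 12 h), where fewer genes were tested, 203 (U 2 h) and 0 (T 12 to 48 h). With arrays centred on their medians they were 71 (U 2 h), 0 (U 12 h) and 107 (T 12 to 48 h).

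With each line left out in turn they ran from 1368 (without U2932) to 1729 (RIVA) for H 2 h and from 2367 (RIVA) to 8309 (NU-DHL-1) for H 12 h, with 2588 (OCI-Ly7) and 2702 (U2932). For L 48 h they ran from 0 (OCI-Ly7) to 158 (U2932), with 14 (RIVA), and for D 12 h from 2138 (RIVA) to 7066 (NU-DHL-1), with 2531 (OCI-Ly7) and 2598 (U2932). For U 2 h they ran from 15 (SU-DHL-5) to 146 (OCI-Ly7), with 20 (NU-DHL-1), 20 (U2932), 27 (FARAGE) and 28 (RIVA), for U 12 h from 0 (FARAGE) to 3 (U2932) and for U 48 h from 0 (OCI-Ly7) to 217 (U2932). For T 2 to 12 h they ran from 1426 (RIVA) to 5698 (NU-DHL-1), with 1723 (OCI-Ly7) and 1852 (U2932). For lines with against without 48 h arrays they ran from 0 (FARAGE) to 2 (OCI-Ly7) at 2 h and from 0 (NU-DHL-1) to 18 (FARAGE) at 12 h, with 1 (RIVA). Where 1 line was left, the joint fit was used and the lone sample was assumed to vary like the other groups: 5863 and 11233 (H 48 h), 6063 and 11600 (D 48 h) and 968 and 5258 (T 12 to 48 h), without RIVA and without U2932. The difference in the size of the response between doses at 2 h ran from 0.0670 without FARAGE to 0.0841 without SU-DHL-5, with an exact p of 0.0625, the smallest that 5 lines allow.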

Other observations

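The values of this part describe untreated cells, carry no test, and were chosen after they were seen. Of the germinal centre genes, BCL6, MYBL1, MME and S1PR2 were lowest in NU-DHL-1 before any drug was added, while LMO2 and SERPINA9 were not. BCL6 stood at 9.38 ± 0.39 (SD over 3 arrays of the line at 0, 2 and 12 h) in NU-DHL-1 and between 11.77 in RIVA and 12.60 in SU-DHL-5 elsewhere. MYBL1 stood at 3.72 ± 0.62 in NU-DHL-1 and between 9.40 in RIVA and 11.42 in SU-DHL-5 elsewhere. MME was lowest in NU-DHL-1 (5.04) and highest in SU-DHL-5 (8.66), and S1PR2 went from 5.94 in NU-DHL-1 to 9.81 in SU-DHL-5. LMO2 ran from 5.05 in RIVA to 12.23 in FARAGE, and SERPINA9 stood at 5.73 in OCI-Ly7, 5.73 in NU-DHL-1 and 5.90 in RIVA and between 8.55 and 9.42 in the other lines.

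Genes of activated B cells and of survival also differed. IRF4 ran from 5.10 ± 0.19 in SU-DHL-5 to 11.89 ± 0.74 in RIVA, FOXP1 from 4.67 ± 0.15 in FARAGE to 11.93 in RIVA, BATF from 5.86 in SU-DHL-5 to 10.73 in RIVA and PIM1 from 6.70 in NU-DHL-1 to 10.43 in RIVA. BCL2 was near background in OCI-Ly7 (3.25) and low in SU-DHL-5 (4.86), against 12.76 in RIVA and 12.38 in U2932. MYC was lowest in U2932, at 7.998, and between 10.58 in SU-DHL-5 and 11.98 in NU-DHL-1 elsewhere.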
